A study of Mus musculus with 12 samples.

How the data were processed

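The series holds 12 arrays of RNA from DKO172 cells, a mouse line derived from a fallopian tumor, in 4 groups of 3: cells given a plasmid coding for wild-type DICER1 (WT), for DICER1 D1709N, for DICER1 G1809R, or for GFP. Per the labels' protocols, 200000 cells per well were plated the day before transfection with 2 µg of plasmid, re-plated after 24 h, kept in hygromycin at 300 µg/ml for 84 h and harvested 108 h after transfection. Per the labels' protocols, 100 ng of total RNA was labelled with Cy3 and hybridized to an Agilent mouse whole-genome array.

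The scanner files were made with Agilent Feature Extraction 11.0.1.1, per the file headers, and give for each spot a background-subtracted and detrended intensity, the raw median intensity of the spot and of its local background, and flags of 0 or 1 for other properties (well above background, saturated, non-uniform). No scaling between arrays had been applied to these intensities, per the file headers. The deposited value table holds log2 signals of 31362 probes, of which 31334 match non-control probes of the scanner files. How the log2 values of that deposited table were scaled is not given in the sources used here. Their medians were 9.42, 9.41 and 9.40 for D1709N replicates 1, 2 and 3, 9.41 for WT replicates 2 and 3, and 9.42 for WT replicate 1 and all G1809R and GFP arrays, so the normalization of the table stays unknown. Their correlation with the log2 scanner intensity was 0.995 for WT replicate 1 and over 0.999 for the other arrays. The value table served only as an alternative.

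For the main analysis the log2 processed intensity of each spot was taken relative to the 75th percentile of the array's 59305 non-control spots, so every level printed is on that scale. The 3671 control spots were left out. The 75th percentile itself lay at 1291, 1152 and 1151 for D1709N replicates 1 to 3, 1387, 1182 and 1208 for G1809R, 1301, 1337 and 1346 for GFP and 1036, 1462 and 1192 for WT. Spots of a probe were averaged without those flagged as outliers (non-uniform, or far from the probe's other spots), and 287 of 55681 probes were left out because all their spots on an array carried such a flag. A probe counted as well above background where at least 1 in 2 of its spots were. No non-control probe was saturated. Probes were kept where they were well above background on every array of at least 1 group (33023), and the probe with the highest mean over the 12 arrays stood for its gene. This left 24183 genes or transcripts, 14731 with a RefSeq symbol and 9452 without. Genes whose signal lay near background are limited by it. Where a gene was not well above background in a group, the fold is given as at least the ratio of the bright group's mean to a floor. The floor is the mean, over the arrays of the dim group, of the higher of the array's lowest signal well above background and the probe's own signal.

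Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with default settings), with the package data.table (version 1.17.8) to read the files. The 12 arrays entered 1 fit with the group as the only factor. The comparisons were each DICER1 construct against GFP, each mutant against WT, the mutants against each other, and the mean of the mutants against WT. P-values were adjusted by Benjamini and Hochberg over all genes within a comparison and called under 0.05. All tests are two-sided. Errors of levels are SDs of 3 arrays, errors of gene changes are SEs from limma, and errors of list means are SDs of the 3 pairs of arrays with the same replicate number.

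Gene lists were fixed before the data were examined: 14 lists of textbook miRNA targets, 7 of 5p and 7 of 3p families, the unions of each arm, and 21 lists of pathways and cell type markers, of 683 symbols in total, 604 of them tested. The lists overlap in their genes. Lists were tested with limma's camera, with the inter-gene correlation preset at 0.01 and, beside it, estimated, and adjusted over the 37 lists of a comparison. Lists of fewer than 3 measured members were not to be tested, and none was. A list's shift is the mean of its members less that of all other genes. No called list had a mean, median and shift of different signs. A test on matches to miRNA seeds in 3' untranslated regions was planned and not run, because no such sequence was among the references.

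The genes named in a comparison follow a rule written with the design: the 8 largest rises and falls among called genes whose arrays do not overlap between the groups and whose symbol is not a clone or locus number, up to 3 members of each list that passed and of let-7, and Dicer1, Hmga2, Lin28b, Igf2bp1, Igf2bp2, Igf2bp3, Zeb1, Zeb2, H19, Igf2 and Cdkn1a where measured. A further gene that the rule names is not reported here. Where no gene passed, the 5 with the smallest p are given by value. The text prints a selection of these, and members called with the replicate block were added after the values were seen.

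The groups share replicate numbers. Replicate 1 of each group lay on slide 1, scanned on 1 day, and replicates 2 and 3 in rows 1 and 2 of slide 2. The residuals of arrays with the same number correlated in 18 of 18 pairs (r from 0.60 to 0.85, all over 0.1), arrays of different numbers at −0.67 to 0.20, and 12 of 12 arrays lay closest to their own number. The first principal component, with 51.6% of the variance, separated the slides (at least 28.8 on slide 2, at most −61.9 on slide 1). The numbers pair the arrays, by sample or position, and the fit with the number as a block is given beside results it changes. Alternatives were quantile normalization, normexp background correction of the raw medians with an offset of 50, the deposited log2 table, no filter on dim probes, a filter over all 12 arrays, all probes or the mean of a gene's probes, trend and robust moderation, a replicate or slide block, slide 2 alone, only the groups compared, a fold limit of 2, fry in place of camera, and each array left out in turn. The normexp alternative had been planned on spot means, which the files do not hold. The replicate block without WT replicate 1 was added after that array was seen to stand apart.

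The scripts were tested on simulated data made from the WT and GFP arrays. Without the block, 0 of 67 genes changed by log2 0.5, 23 of 67 by 1 and 48 of 66 by 2 were recovered, with 0 false calls. With the block 14, 45 and 63 were, with 8 false calls. The unchanged comparison, D1709N against GFP, gave 0 calls. A let-7 list lowered by 0.5 gave a mean of −0.54 and passed, and 0 of 22 lists sharing no gene with it did. This was no test of the preset correlation. Shared controls were simulated with 100 data sets of unchanged groups.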

Results

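RNA from DKO172 cells, a mouse line derived from a fallopian tumor of a female animal, was measured on 12 single-colour Agilent whole-genome arrays. The line's own Dicer1 gene is recorded as knocked out. The cells had been transfected with a hygromycin-selectable plasmid coding for wild-type DICER1 (WT), for DICER1 with the hotspot substitution D1709N or G1809R, or for GFP as the control, with 3 arrays in each of the 4 groups. DICER1 is the RNase III enzyme that cuts miRNA precursors, and the hotspot residues lie in its RNase IIIb domain, which cuts the strand that gives 5p miRNAs. The comparisons ask which genes change when each construct is expressed and how the mutants differ from the wild type. Replicate 1 of every group lay on slide 1 and replicates 2 and 3 on slide 2. On slide 1, 68.1% (D1709N), 68.9% (G1809R), 71.3% (GFP) and 82.7% (WT) of the probes were well above background. On slide 2 the values were 57.5% and 49.4% for D1709N, 62.3% and 61.8% for G1809R, 62.6% and 55.0% for GFP, and 58.7% and 54.2% for WT. WT replicate 1 stood apart: it had the highest share above background, and its correlation with the other WT arrays was 0.977 to 0.980, against 0.981 to 0.993 between the other pairs of arrays of 1 group. The number of arrays limits the precision. Whether the replicates were separate cultures is not stated, so each p-value measures the spread between these samples, which may be technical.

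The array holds 1 probe for Dicer1, of the mouse gene. Whether the plasmids' inserts contain the probed part is not given in the sources used here. The probe therefore checks no label and does not measure how much DICER1 a plasmid gave. Its log2 level, relative to the 75th percentile of each array, was 1.13 ± 0.20 (SD, n = 3) with GFP, 0.27 ± 0.23 with WT, 0.82 ± 0.18 with D1709N and 0.92 ± 0.24 with G1809R. The probe's signal fell with WT (log2 change −0.86 ± 0.18 SE, limma adjusted p = 0.035, lower in 3 of 3 pairs of the same replicate number). This call was lost without D1709N replicate 1 (adjusted p = 0.052) or 2 (0.0547), G1809R replicate 2 (0.0524), GFP replicate 1 (0.126), 2 (0.0669) or 3 (0.0995), or WT replicate 2 (0.126) or 3 (0.0845). The signal was not called with D1709N (−0.31, adjusted p = 0.785) or with G1809R (−0.21, adjusted p = 1). Against WT it was at 0.54 ± 0.18 with D1709N (adjusted p = 0.188, 0.0096 with the replicate block) and 0.65 ± 0.18 with G1809R (0.119, 0.00507 with the block).

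With wild-type DICER1, the genes that fell most against GFP included the let-7 targets Lin28b, Lin28a and Nr6a1. Lin28b and Lin28a are RNA-binding proteins that block let-7 maturation, and Nr6a1 is an orphan nuclear receptor. Lin28b fell 6.48-fold, from a log2 level of 3.64 ± 0.25 (SD, n = 3) to 0.95 ± 0.05, Lin28a fell 5.87-fold from 3.66 ± 0.32 to 1.11 ± 0.36, and Nr6a1 fell 6.08-fold from 0.95 ± 0.31 to −1.65 ± 0.32. Genes of the cell cycle fell as a group, while interferon-stimulated genes rose, with Oasl1 17.8-fold and Ifih1, a sensor of double-stranded RNA, 10.3-fold higher. For interferon genes 6 of 36 members were called, and adjusted p = 0.215 with an estimated correlation. Each of the gene and group changes named had the same direction in 3 of 3 pairs.

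Of 24183 genes and transcripts tested with limma, 713 changed between WT and GFP, 287 higher and 426 lower, and 239 of them by at least 2-fold. With the replicate number as a block the count was 4300, 2219 higher and 2081 lower, and all 713 were among them. With the slide as a block it was 2112. It was 206 without the filter on dim probes and 3 with only WT and GFP in the fit. On slide 2 alone it was 3, all of which had the same sign on slide 1. Across all genes the log2 changes on the slides correlated with r = 0.62 (genes are not independent replicates). Leaving out a single array gave 146 genes without GFP replicate 3, 201 without GFP replicate 1, 226 without WT replicate 2, 290 without WT replicate 1, 386 without GFP replicate 2 and 443 without D1709N replicate 3.

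The let-7 list, of textbook targets of a 5p family, fell by a mean log2 of −0.61 ± 0.05 (SD of 3 pairs, lower in 3 of 3, camera adjusted p = 1.46e-17). Of 45 measured members 14 fell, 1 rose and 30 were not called. Adjusted over the list alone 22 fell and 1 rose, and with the replicate block 23 fell and 3 rose. Lin28b (−2.70 ± 0.25 SE, adjusted p = 0.00173), Nr6a1 (−2.61 ± 0.27, adjusted p = 0.00221) and Lin28a (−2.55 ± 0.28, adjusted p = 0.00368) were called in every fit that left out 1 array. Hmga2, a chromatin protein and let-7 target, was at −0.61 ± 0.18 (adjusted p = 0.122, 0.0223 with the replicate block). Igf2bp1 was at −0.69 ± 0.25 (0.209, 0.00319 with the block), Igf2bp3 at −0.57 ± 0.24 (0.302), Zeb1 at −0.54 ± 0.13 (0.0678, 0.00589 with the block) and the imprinted RNA H19 at −0.07 ± 0.41 (0.999). The union of the 7 lists of 5p targets fell (mean −0.31 ± 0.04, 3 of 3 pairs, adjusted p = 7.18e-13), with 21 of 163 members lower and 1 higher. Adjusted over the list alone these were 34 and 2, and with the replicate block 51 and 7. The let-7, 5p and miR-30 lists kept their calls with an estimated correlation, at adjusted p = 0.0153, 0.0307 and 0.0478. In the blocked fit the estimated correlation gave 0.0546 for each.

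Each of the other 5p lists fell as well in 3 of 3 pairs. Means were −0.30 ± 0.05 for miR-21 targets, −0.28 ± 0.04 for miR-15/16, −0.27 ± 0.04 for miR-30, −0.18 ± 0.08 for miR-31, −0.16 ± 0.05 for miR-34 and −0.14 ± 0.08 for miR-17 family, with adjusted p from 4.67e-05 to 0.0236. With an estimated correlation, adjusted p = 0.0727 for miR-21, 0.104 for miR-15/16 and miR-31, and 0.215 for miR-34 and miR-17 family. The miR-31 call was lost without GFP replicate 3 (0.076). The miR-17 family call was lost without GFP replicate 2 (0.0737) or WT replicate 1 (0.168). Reck, an inhibitor of matrix metalloproteases on the miR-21 list, fell by 1.47 on the log2 scale (± 0.20 SE, adjusted p = 0.0066), Wee1, the kinase that restrains CDK1 and a miR-15/16 target, by 1.03 (± 0.10, adjusted p = 0.00211), and Hif1an of the miR-31 list by 1.40 (± 0.21, adjusted p = 0.01), each lower in 3 of 3 pairs. Tnrc6a, the Argonaute partner also known as GW182, fell by 1.17 (± 0.12, adjusted p = 0.00211) and is on the miR-30 list and on the list of miRNA processing and silencing factors. That list fell (mean −0.43 ± 0.05, 6 of 22 members lower, adjusted p = 1.01e-05), but it holds the let-7 targets Lin28a and Lin28b, and without them the mean was −0.21 (4 of 20 lower, adjusted p = 0.00122, and adjusted p = 0.104 with an estimated correlation). With all 22 it counted 9 lower and 1 higher adjusted over the list alone and 10 lower and 2 higher with the block, and adjusted p = 0.0478 with an estimated correlation (0.108 with the block as well).

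The union of the 7 lists of 3p targets fell less (mean −0.11 ± 0.03, 3 of 3 pairs, adjusted p = 0.00139, and adjusted p = 0.215 with an estimated correlation). Of 100 members 9 fell and 2 rose, 15 and 3 adjusted over the list alone, and 27 and 10 with the replicate block. Within it the miR-101 list fell (−0.38 ± 0.04, adjusted p = 1.94e-05, and adjusted p = 0.104 with an estimated correlation), and so did the miR-221 list (targets of miR-221 and its paralogue, −0.34 ± 0.04, adjusted p = 0.036, and adjusted p = 0.382 with an estimated correlation). The latter call was lost without GFP replicate 1 (0.109), WT replicate 2 (0.0515) or WT replicate 3 (0.142). The lists for miR-25/92 (−0.20), miR-19 (−0.10), miR-27 (−0.09), miR-200 (−0.08) and miR-29 (0.06) did not pass, with adjusted p between 0.0784 and 0.497, and for miR-29 the shift against other genes, −0.01, had the opposite sign to the mean. Tet2, a 5-methylcytosine dioxygenase and miR-29 target, fell by 1.20 on the log2 scale (± 0.16 SE, adjusted p = 0.0074, 3 of 3 pairs), whereas the collagens Col4a2 and Col5a3, also miR-29 targets, rose by 1.31 ± 0.30 (adjusted p = 0.0496) and 1.24 ± 0.26 (adjusted p = 0.0366). The Col4a2 call was lost without any array but WT replicate 1 (0.169 without GFP replicate 1), and the Col5a3 call without D1709N replicate 1 (0.0565), G1809R replicate 1 (0.0528), GFP replicate 1 (0.131), 2 (0.0752) or 3 (0.105), or WT replicate 1 (0.108), 2 (0.0989) or 3 (0.0766).

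**Figure D1:**
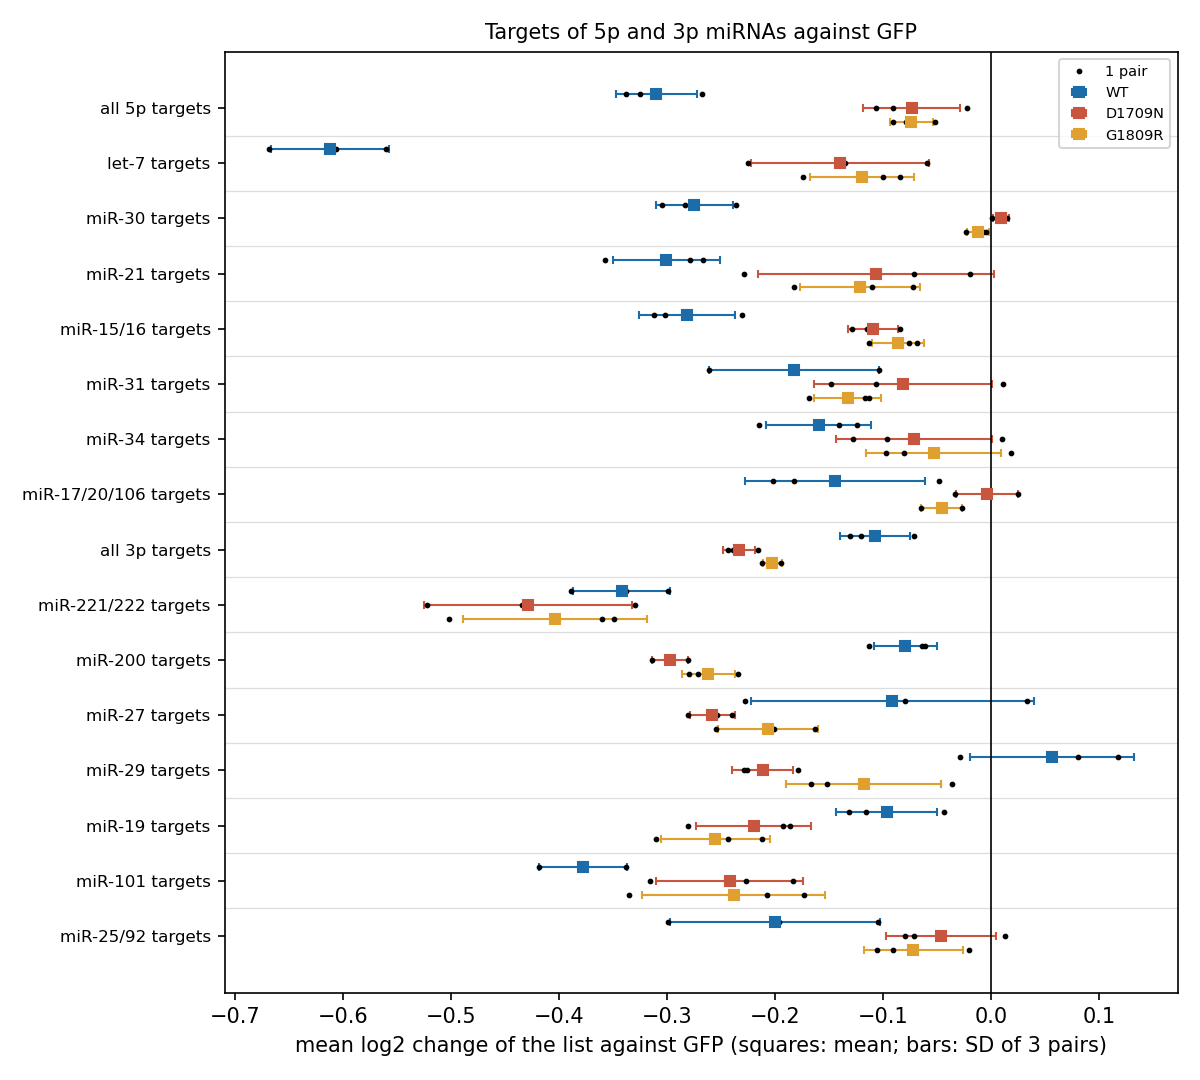
Mean log2 change against GFP of the unions and lists of 5p and 3p miRNA targets for WT, D1709N and G1809R. Squares and bars are the mean and SD of 3 pairs of arrays of the same replicate number and black points are single pairs; all 5p targets lie at −0.31 with WT and −0.07 with each mutant, and all 3p targets at −0.11, −0.23 and −0.20.

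S phase and mitosis genes fell with WT by a mean of −0.63 ± 0.12 (SD of 3 pairs, 3 of 3, adjusted p = 4.63e-30, and adjusted p = 0.00656 with an estimated correlation, or 0.0546 with the block as well). Of 47 measured members 17 fell and 30 were not called. Adjusted over the list alone 35 fell, and with the replicate block 38 did. Ccna2, the cyclin of S phase, fell by 1.15 (± 0.11 SE, adjusted p = 0.00193), Cdc25a, the phosphatase that activates CDKs, by 1.20 (± 0.14, adjusted p = 0.00422) and the transcription factor E2f2 by 1.52 (± 0.26, adjusted p = 0.0173), each in 3 of 3 pairs. The E2f2 call was lost without GFP replicate 1 (0.0739), GFP replicate 3 (0.0825) or WT replicate 2 (0.0709). Cdkn1a, the CDK inhibitor p21, was at 0.31 ± 0.15 (adjusted p = 0.4).

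Interferon-stimulated genes rose with WT by a mean of 2.66 ± 0.97 (SD of 3 pairs, adjusted p = 3.81e-22, and adjusted p = 0.215 with an estimated correlation). The pairs gave 3.77 for replicate 1, on slide 1, where WT replicate 1 stood apart, and 2.15 and 2.05 on slide 2. Of 36 members 6 rose and 30 were not called, though all 36 lay above 0. Adjusted over the list alone 32 rose, and with the replicate block 34 did. Oasl1 rose by 4.16 (± 0.84 SE, adjusted p = 0.0318), Ifih1 by 3.36 (± 0.73, adjusted p = 0.041) and the guanylate-binding protein gene Gbp2 by 3.27 (± 0.67, adjusted p = 0.0349). All 3 calls were lost without GFP replicate 1, GFP replicate 3, WT replicate 1, WT replicate 2, D1709N replicate 3 or G1809R replicate 3, with Ifih1 at 0.152, Gbp2 at 0.13 and Oasl1 at 0.123 without GFP replicate 3. Without D1709N replicate 1 the calls of Ifih1 (0.0574) and Gbp2 (0.0521) were lost as well, and that of Ifih1 also without D1709N replicate 2 (0.0508) or G1809R replicate 1 (0.0605). Ifnb1, interferon beta itself, rose in 3 of 3 pairs (adjusted p = 0.00783), and no fold is given because it was above background on 3 WT arrays but on 1 GFP array. Cd200r2 rose at least 7.92-fold (adjusted p = 0.0074). It was not well above background with GFP, and the bound uses the floor defined above.

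Among other lists, oncofetal and imprinted genes fell with WT (mean −0.53 ± 0.04, 4 of 17 members lower, adjusted p = 0.00011, and adjusted p = 0.149 with an estimated correlation). Of these 6 are let-7 targets, and without them the call was lost (mean −0.10, adjusted p = 0.371). In the full list the mRNA-binding protein gene Igf2bp2 fell (−0.80 ± 0.17, adjusted p = 0.0358). The Igf2bp2 call was lost in 9 of the 12 fits that left out 1 array, those without D1709N replicate 1 (0.0536), 2 (0.0509) or 3 (0.0597), G1809R replicate 3 (0.0565), GFP replicate 2 (0.0922) or 3 (0.118), or WT replicate 1 (0.111), 2 (0.0747) or 3 (0.0709). NF-kB and inflammatory genes (−0.35 ± 0.19, adjusted p = 0.00941), cholesterol synthesis (−0.18 ± 0.04, adjusted p = 0.0181) and collagen and matrix genes (−0.11 ± 0.05, adjusted p = 0.047) also fell, but with an estimated correlation adjusted p = 0.384, 0.452 and 0.452. The collagen call was lost with the replicate block (0.0619), in which the p53 target list passed (mean −0.13, 0.111 without the block, 0.002 with it, and adjusted p = 0.0986 with an estimated correlation in the blocked fit). Without GFP replicate 3 the adjusted p was 0.155 for NF-kB, 0.148 for cholesterol and 0.213 for collagen. Without WT replicate 1 it was 0.0989 for cholesterol and 0.17 for collagen, and without WT replicate 2 0.0575 for NF-kB and 0.122 for collagen. The collagen call was also lost without D1709N replicate 3 (0.0609) or G1809R replicate 3 (0.0547). The chemokine gene Ccl2, on the NF-kB list, fell by 1.57 (± 0.26 SE, adjusted p = 0.0155), a call lost without GFP replicate 3 (0.0762), WT replicate 1 (0.0542) or WT replicate 2 (0.0646). Lists not called with WT were amino acid stress (0.22), heat shock (0.23), ribosomal proteins (0.08), hypoxia and glycolysis (−0.02), TGF-beta response (0.18), Wnt targets (0.19), mesenchymal (0.06) and epithelial genes (0.09), Muellerian epithelium (0.11), gonadal stroma (0.10), and endothelial (0.24), leukocyte (0.09) and smooth muscle markers (0.22), with adjusted p from 0.0558 to 0.812. For mesenchymal genes the shift against other genes was −0.01.

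**Figure D2:**
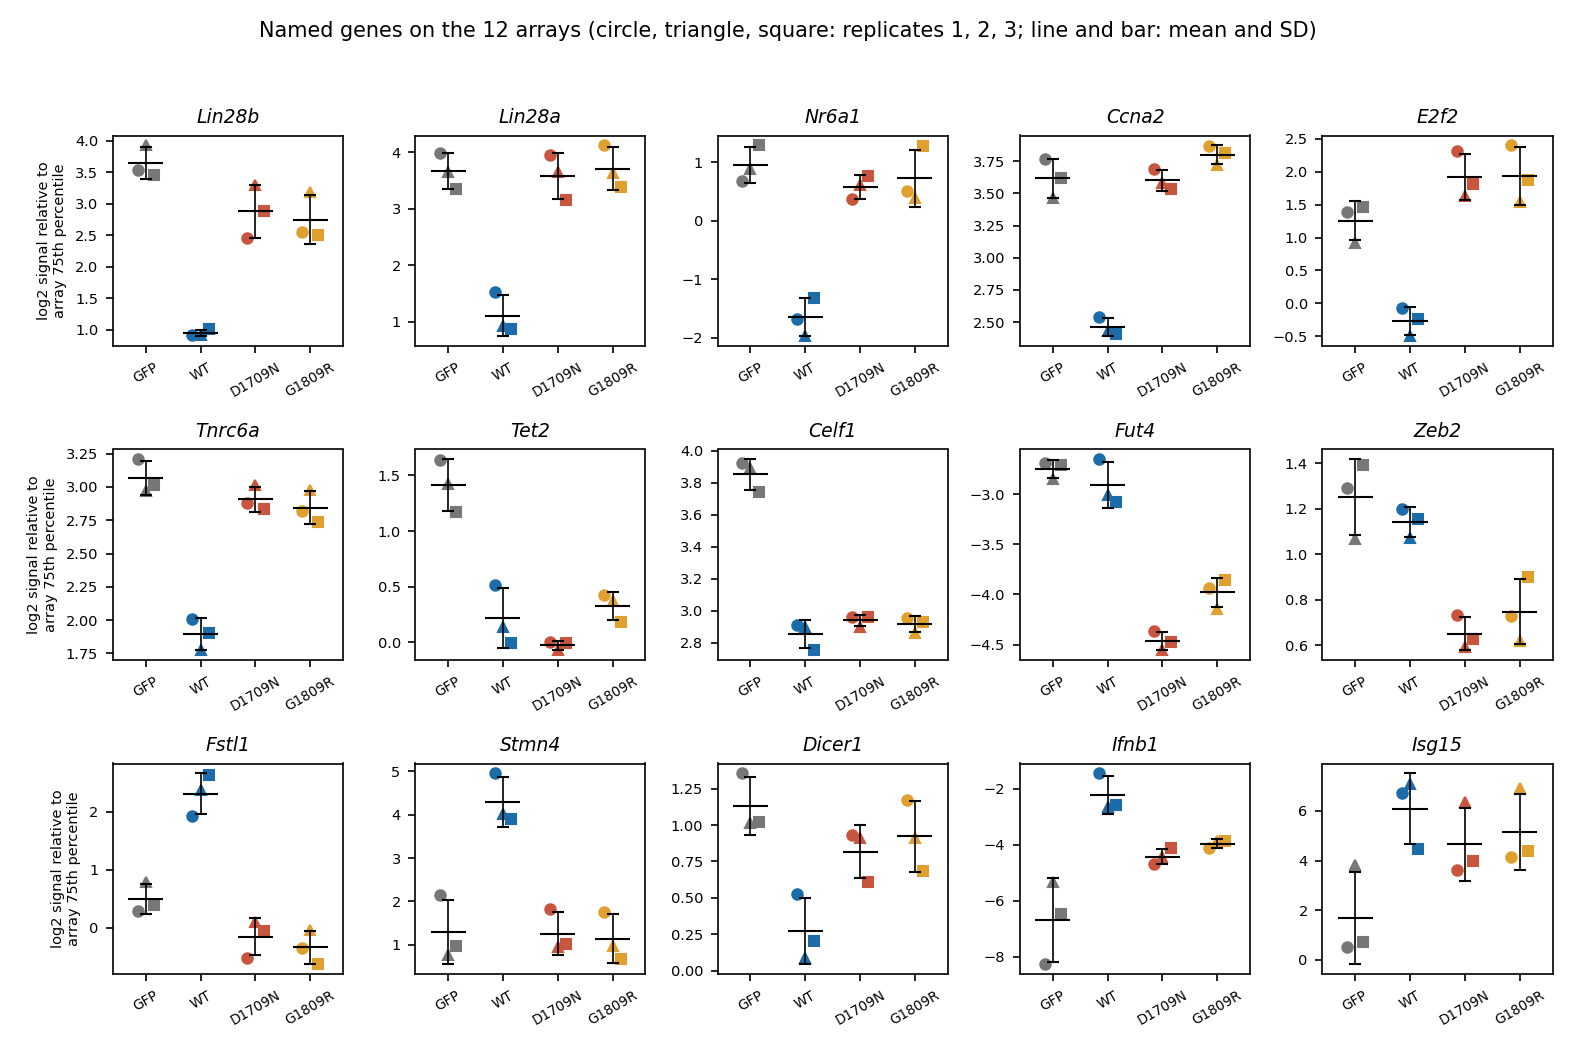
Log2 signal relative to the array's 75th percentile of 15 named genes on the 12 arrays, by group, with circles, triangles and squares for replicates 1, 2 and 3 and a line and bar for the mean and SD. Lin28b lies at 3.64 with GFP, 0.95 with WT, 2.88 with D1709N and 2.75 with G1809R.

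With the replicate block 1028 genes passed the test of D1709N against GFP. Without it few did, and those were mostly lower. Fut4, a fucosyltransferase, fell 3.28-fold (from a log2 level of −2.75 ± 0.09 to −4.46 ± 0.09, SD, n = 3), Tet2 fell 2.71-fold (from 1.41 ± 0.23 to −0.02 ± 0.04) and Celf1, an RNA-binding protein, fell 1.88-fold (from 3.85 ± 0.10 to 2.94 ± 0.03), each in 3 of 3 pairs. Targets of 3p miRNAs fell as a group by a mean log2 of −0.23 ± 0.01, interferon-stimulated genes rose by 1.43 ± 0.11 and cell cycle genes were at 0.05 ± 0.11 and not called. In these lists 1 of 100 and 0 of 36 members were called by limma, and adjusted p = 0.201 for 3p targets and 0.333 for interferon genes with an estimated correlation.

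By limma, 12 of 24183 genes changed with D1709N, 2 higher and 10 lower. An unadjusted p under 0.05 was seen for 1744. With the replicate block 1028 changed, 427 higher and 601 lower, including all 12, and with the slide block 97. The count was 2 without the filter on dim probes and 0 with only D1709N and GFP in the fit. On slide 2 alone 1 gene was called, with the same sign on slide 1. Across genes the log2 changes on the slides correlated with r = 0.43. The count was 2 without D1709N replicate 2 or 3, G1809R replicate 3, any GFP replicate or WT replicate 2, 3 without D1709N replicate 1, and 7 without WT replicate 3. The called genes were Fut4 (−1.71 ± 0.14 SE, adjusted p = 0.00289, called in every fit that left out 1 array), Tet2 (−1.44 ± 0.16, adjusted p = 0.0241), the homeobox gene Six4 (−1.20 ± 0.14, adjusted p = 0.0241), the phosphatase gene Phlpp2 (−1.18 ± 0.13, adjusted p = 0.0241), Tmem101 (−1.07 ± 0.13, adjusted p = 0.0369), Purg (−0.99 ± 0.12, adjusted p = 0.0305), Celf1 (−0.91 ± 0.10, adjusted p = 0.0236) and Dnajc13 (−0.77 ± 0.10, adjusted p = 0.0456). Homer1 (−0.74) and 2310065F04Rik (−6.17), both chosen after their values were seen, and a pair of transcripts without a symbol, both higher, complete the 12. Tet2, Six4, Phlpp2, Tmem101, Purg, Celf1 and Dnajc13 each lost the call without D1709N replicate 2 or 3, G1809R replicate 3, any GFP replicate or WT replicate 2, and all but Six4 without D1709N replicate 1. Without GFP replicate 2 the adjusted p was 0.178 for Tet2, Six4, Phlpp2 and Celf1, 0.209 for Tmem101 and Purg, and 0.286 for Dnajc13. Without the other arrays the calls of Tmem101, Purg and Dnajc13 were lost in part, at up to 0.0878, 0.0672 and 0.0981. The other probe of Tet2 was at −1.47, that of Purg at −0.05 and that of Fut4, dimmer, at −0.34, and the other probes of Celf1 were at −0.23 and −0.54. Fut4 was well above background on 2 of 3 D1709N arrays.

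The union of 3p targets fell with D1709N in 3 of 3 pairs (adjusted p = 1.56e-07, and adjusted p = 0.201 with an estimated correlation, and 0.0392 with an estimated correlation in the replicate-block fit). Of 100 members 1, Tet2, fell. Adjusted over the list alone 7 fell, and with the block 20 fell and 2 rose. The miR-200 list, whose targets include the E-cadherin repressors Zeb1 and Zeb2, fell (mean −0.30 ± 0.02, adjusted p = 2.53e-05) and kept the call with an estimated correlation, at adjusted p = 0.0315. Over all genes 0 of its 25 members were called by limma, adjusted over the list alone 2 fell, and with the block 6 fell and 2 rose. Zeb2 was at −0.60 ± 0.12 (adjusted p = 0.188, 0.0105 with the replicate block, in which it fell), Cyp1b1 was not well above background with D1709N and at least 3.45-fold dimmer than with GFP (adjusted p = 0.446, 0.00571 with the block) and Ets1 was at −0.78 ± 0.15 (adjusted p = 0.176, 0.0102 with the block). The lists for miR-221 (−0.43 ± 0.10), miR-27 (−0.26 ± 0.02), miR-101 (−0.24 ± 0.07), miR-19 (−0.22 ± 0.05) and miR-29 (−0.21 ± 0.03) fell too, with adjusted p from 0.000917 to 0.0124, and adjusted p = 0.265 with an estimated correlation for each. In the blocked fit it was 0.0392 for miR-221 targets. The miR-25/92 list was at −0.05 (adjusted p = 0.411, with a median above 0).

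The union of 5p targets moved less with D1709N (mean −0.07 ± 0.04, adjusted p = 0.021, and adjusted p = 0.34 with an estimated correlation). By limma 0 of its 163 members were called over all genes or over the list alone, and 11 fell with the block. Its call was lost without D1709N replicate 1 (0.186) or GFP replicate 3 (0.16). The let-7 list was at −0.14 ± 0.08 (adjusted p = 0.00327, and adjusted p = 0.265 with an estimated correlation) and lost its call without D1709N replicate 1 (0.0633). Lin28b was at −0.76 ± 0.25 (adjusted p = 0.466, 0.0408 with the block). The miR-15/16 list fell (−0.11 ± 0.02, adjusted p = 0.0357, and adjusted p = 0.333 with an estimated correlation). The miR-31 list (−0.08) passed with the block only (0.0547 without it, 0.0324 with it, and adjusted p = 0.14 with an estimated correlation in the blocked fit). The miR-21 (−0.11), miR-34 (−0.07), miR-30 (0.01) and miR-17 family (−0.00) lists were not called. Without D1709N replicate 1 the adjusted p was 0.0668 for the miR-15/16 and miR-19 lists, 0.0895 for miR-27 and 0.0564 for miR-101. Without GFP replicate 3 it was 0.116 for miR-15/16, 0.0662 for miR-29, 0.059 for miR-19 and 0.0721 for miR-101. Without D1709N replicate 2 it was 0.153 for miR-15/16, 0.0711 for miR-29 and 0.0705 for miR-19. Without GFP replicate 1 it was 0.0825 for miR-15/16.

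Interferon-stimulated genes rose with D1709N in 3 of 3 pairs (adjusted p = 5.82e-12, and adjusted p = 0.333 with an estimated correlation). By limma 0 of the 36 members were called over all genes or over the list alone, and 13 rose with the block, among them the ubiquitin-like Isg15 (2.98 ± 1.17 SE, adjusted p = 0.607, 0.0235 with the block). Ribosomal protein genes (0.22 ± 0.07, adjusted p = 1.39e-07), hypoxia and glycolysis genes (0.34 ± 0.12, adjusted p = 3.34e-07), amino acid stress genes (0.23 ± 0.03, adjusted p = 0.00575) and heat shock genes (0.18 ± 0.05, adjusted p = 0.0409) rose, with an estimated correlation adjusted p = 0.384, 0.265, 0.333 and 0.384. NF-kB genes (−0.36 ± 0.14, adjusted p = 0.000206), mesenchymal genes (−0.29 ± 0.06, adjusted p = 0.000518), collagen and matrix genes (−0.23 ± 0.06, adjusted p = 0.00349), oncofetal genes (−0.28 ± 0.10, adjusted p = 0.00704) and p53 targets (−0.15 ± 0.02, adjusted p = 0.0124) fell, with an estimated correlation adjusted p = 0.265, 0.265, 0.333, 0.318 and 0.557. For mesenchymal genes it was 0.0392 in the blocked fit. The smooth muscle and fibroblast markers (−0.25) passed with the replicate block only (0.315 without it, 0.044 with it, and adjusted p = 0.265 with an estimated correlation in the blocked fit). Leaving out 1 array ended the calls for p53 targets (0.42 without D1709N replicate 3, 0.422 without GFP replicate 2), heat shock (0.114 and 0.205 without D1709N replicates 2 and 3, 0.326 without GFP replicate 1), amino acid stress (0.244 without GFP replicate 1), oncofetal genes (0.0548 without GFP replicate 1), NF-kB genes (0.0522 without GFP replicate 3) and collagen (0.0818 without D1709N replicate 2, 0.108 without GFP replicate 3).

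With G1809R the picture against GFP was close in size. Fut4 fell 2.34-fold (from a log2 level of −2.75 ± 0.09 to −3.98 ± 0.15, SD, n = 3) and Celf1 fell 1.91-fold (from 3.85 ± 0.10 to 2.92 ± 0.05), each in 3 of 3 pairs. Targets of 3p miRNAs fell by a mean log2 of −0.20 ± 0.01, interferon-stimulated genes rose by 1.90 ± 0.10, and cell cycle genes were at 0.09 ± 0.08 and not called (adjusted p = 0.0816). In these lists 0 of 100 and 0 of 36 members were called by limma, and adjusted p = 0.162 for 3p targets and 0.244 for interferon genes with an estimated correlation.

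By limma 3 of 24183 genes changed with G1809R, all lower, and 1605 had an unadjusted p under 0.05. They were Fut4 (−1.23 ± 0.14 SE, adjusted p = 0.0393), Celf1 (−0.94 ± 0.10, adjusted p = 0.028) and 2310065F04Rik (−6.32), the last chosen after its values were seen. The replicate block gave 904 genes, 424 higher and 480 lower, including all 3, and the slide block 63. Without the filter on dim probes, or with only G1809R and GFP in the fit, it was 1. On slide 2 alone the count was 1, with the same sign on slide 1, and r between the slides was 0.51 across genes. Without WT replicate 1 the count was 2, and without any other array it was 1. Celf1 lost its call whichever of the 12 arrays was left out (0.186 without GFP replicate 2), and Fut4 whichever but WT replicate 1 (0.268 without GFP replicate 3). Tet2 was at −1.08 ± 0.16 (adjusted p = 0.13, 0.00807 with the block), Zeb2 at −0.50 ± 0.12 (adjusted p = 0.346, 0.0222 with the block), and Lin28b at −0.89 ± 0.25 (adjusted p = 0.449, 0.0291 with the block). The other probes of Celf1 were at −0.24 and −0.53 and that of Fut4 at 0.13.

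The union of 3p targets fell with G1809R in 3 of 3 pairs (adjusted p = 9.58e-08, and adjusted p = 0.162 with an estimated correlation, and 0.0322 with an estimated correlation in the replicate-block fit). By limma 0 of 100 members were called, adjusted over the list alone 7 fell, and with the block 16 fell and 2 rose. The miR-200 list fell (−0.26 ± 0.02, adjusted p = 5.96e-05) and kept the call at adjusted p = 0.0378 with an estimated correlation, with 0 of 25 members called over all genes, 2 lower adjusted over the list alone, and 5 lower and 1 higher with the block. The miR-221 (−0.40 ± 0.09), miR-19 (−0.26 ± 0.05), miR-101 (−0.24 ± 0.09), miR-27 (−0.21 ± 0.05) and miR-29 (−0.12 ± 0.07) lists fell, with adjusted p from 0.000763 to 0.00772, and with an estimated correlation adjusted p = 0.203, 0.174, 0.244, 0.174 and 0.278. In the blocked fit it was 0.0338 for miR-221 and 0.0462 for miR-19 targets. The miR-25/92 list was at −0.07 (adjusted p = 0.21).

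The union of 5p targets was at −0.07 ± 0.02 with G1809R (lower in 3 of 3 pairs, adjusted p = 0.00421, and adjusted p = 0.278 with an estimated correlation). By limma 0 of 163 members were called over all genes or over the list alone, and 7 fell and 1 rose with the block. The let-7 (−0.12 ± 0.05, adjusted p = 0.00645), miR-31 (−0.13 ± 0.03, adjusted p = 0.00642), miR-21 (−0.12 ± 0.06, adjusted p = 0.0247) and miR-15/16 (−0.09 ± 0.02, adjusted p = 0.0289) lists fell, with an estimated correlation adjusted p = 0.278, 0.162, 0.274 and 0.296. The miR-34 (−0.05), miR-17 family (−0.05, with a median above 0) and miR-30 (−0.01) lists were not called. Without G1809R replicate 2 the adjusted p was 0.0532 for all 5p targets, 0.0792 for let-7, 0.0584 for miR-31, 0.148 for miR-21, 0.258 for miR-15/16, 0.143 for miR-29 and 0.0516 for miR-19. Without GFP replicate 3 it was 0.0683 for all 5p targets, let-7, miR-31, miR-21 and miR-101, 0.102 for miR-15/16 and 0.109 for miR-29. Without G1809R replicate 1 it was 0.0534 for let-7 and 0.0526 for miR-21 and miR-31. Without GFP replicate 1 it was 0.0881 for miR-15/16 and 0.102 for miR-21.

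Interferon-stimulated genes rose with G1809R in 3 of 3 pairs (adjusted p = 1.64e-21, and adjusted p = 0.244 with an estimated correlation). By limma 0 of 36 were called over all genes, 8 rose adjusted over the list alone, and 27 rose with the block, among them Isg15 (3.49 ± 1.17 SE, adjusted p = 0.558, 0.0167 with the block). Hypoxia and glycolysis (0.23 ± 0.13, adjusted p = 0.000763), amino acid stress (0.23 ± 0.05, adjusted p = 0.00419) and ribosomal protein genes (0.12 ± 0.15, adjusted p = 0.00419, but a shift of −0.01 under normexp or quantile scaling) rose, with an estimated correlation adjusted p = 0.327, 0.293 and 0.557. For ribosomal proteins replicate 1, on slide 1, lay at −0.05 against 0.25 and 0.16 on slide 2, and the shift against other genes was −0.07 without GFP replicate 1 (adjusted p = 0.539), −0.06 without G1809R replicate 2 (0.984) and −0.01 without G1809R replicate 3 (0.157). NF-kB (−0.40 ± 0.08, adjusted p = 5.56e-05), mesenchymal (−0.24 ± 0.08, adjusted p = 0.000763), collagen (−0.16 ± 0.10, adjusted p = 0.00392), p53 (−0.15 ± 0.04, adjusted p = 0.00419), oncofetal (−0.24 ± 0.04, adjusted p = 0.00586), TGF-beta (−0.18 ± 0.04, adjusted p = 0.0175) and Wnt target genes (−0.22 ± 0.08, adjusted p = 0.0274) fell, with an estimated correlation adjusted p = 0.244, 0.177, 0.296, 0.436, 0.278, 0.351 and 0.198. In the blocked fit it was 0.0338 for mesenchymal genes and 0.0462 for p53 targets. The smooth muscle and fibroblast markers (−0.30 ± 0.27) passed with the block only (0.158 without it, 0.00913 with it, and adjusted p = 0.143 with an estimated correlation in the blocked fit). Without G1809R replicate 2 the adjusted p was 0.0985 for oncofetal, 0.0532 for amino acid stress, 0.306 for TGF-beta, 0.113 for Wnt and 0.214 for collagen genes. Without GFP replicate 3 it was 0.281 for TGF-beta, 0.154 for Wnt and 0.102 for collagen. Without G1809R replicate 1 it was 0.0755 for TGF-beta and 0.0597 for Wnt. Without GFP replicate 1 it was 0.0567 for oncofetal and 0.189 for amino acid stress genes. The p53 targets stood at 0.191 without G1809R replicate 3 and 0.246 without GFP replicate 2.

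**Figure D3:**
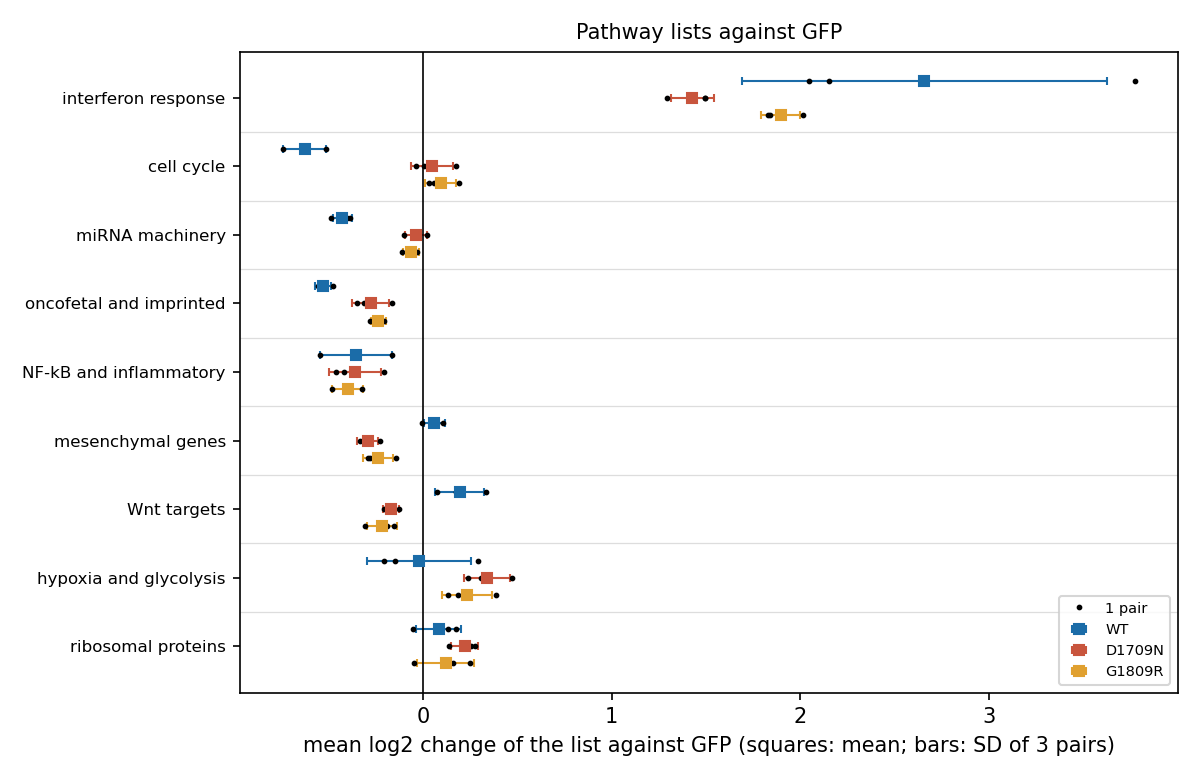
Mean log2 change against GFP of 9 pathway lists for WT, D1709N and G1809R, with squares and bars for the mean and SD of 3 pairs of arrays of the same replicate number and black points for single pairs. Interferon-stimulated genes lie at 2.66, 1.43 and 1.90, and cell cycle genes at −0.63, 0.05 and 0.09.

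The comparisons share their controls. Log2 changes of D1709N and G1809R, both against GFP, correlated across 24183 genes with r = 0.79 (covariance 0.0852), where unchanged groups simulated against shared controls gave r = 0.50 (covariance 0.0214). For WT and the mean of the mutants against GFP r was 0.58 (covariance 0.0821), with 0.58 simulated (covariance 0.0214). Genes are not independent replicates. All 3 genes lower with G1809R (Fut4, Celf1 and 2310065F04Rik) were lower with D1709N, where independent lists would share 0.00124. With WT, D1709N shared 2 higher and 8 lower genes (0.0237 and 0.176 for independent lists) and G1809R shared 2 lower genes (0.0528). In the blocked fit, D1709N and G1809R shared 257 higher and 371 lower genes (7.49 and 11.9), none in opposite directions. WT and D1709N shared 264 higher and 295 lower (39.2 and 51.7), with 50 opposite (91.9). WT and G1809R shared 297 higher and 248 lower (38.9 and 41.3), with 43 opposite (80.5). Simulated unchanged groups shared at most 1 gene, but groups without effects have few calls to share, so this is no reference for the overlaps. Part of the excess may come from the shared controls, whose 3 arrays cannot be split into parts of 2 each.

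Against WT directly, both mutants had higher levels of the let-7 targets and cell cycle genes as lists. With D1709N and G1809R, limma called 7 and 8 of 45 let-7 targets and 16 and 18 of 47 cell cycle genes, and the let-7 call for D1709N was lost at adjusted p = 0.0511 with an estimated correlation. Both lists kept their calls with the replicate block alone. With the block and an estimated correlation together they lost them (camera adjusted p = 0.108 and 0.0917). Lin28a was 5.54-fold higher with D1709N and 6.06-fold with G1809R (log2 levels 3.58 ± 0.41 and 3.71 ± 0.38 against 1.11 ± 0.36 with WT, SD, n = 3), Nr6a1 was 4.7-fold and 5.19-fold higher, and E2f2 4.56-fold and 4.62-fold higher. Fstl1, a secreted glycoprotein, was 5.52-fold and 6.27-fold lower (−0.16 ± 0.32 and −0.34 ± 0.29 against 2.31 ± 0.36), and Stmn4, a microtubule-destabilizing protein of the stathmin family, 8.14-fold and 8.87-fold lower. Each of these 5 genes had its direction in 3 of 3 pairs for both mutants.

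By limma 402 genes differed between D1709N and WT, 240 higher and 162 lower, and 397 between G1809R and WT, 251 higher and 146 lower. The mean of the mutants differed from WT in 872 genes, 528 higher and 344 lower. With only the groups compared in the fit the counts were 0, 0 and 461, and without the filter on dim probes 55, 68 and 344. The replicate block gave 3760, 3065 and 4713, including every gene called without it, and the slide block 1407, 1206 and 2213. The excess of higher genes was not kept with the replicate block (1723 higher and 2037 lower, 1538 and 1527, and 2305 and 2408) or among genes changed by at least 2-fold (61 and 90, 64 and 83, and 80 and 132). On slide 2 alone they were 3, 11 and 54, of which 1, 10 and 53 had the same sign on slide 1, with r between the slides of 0.46, 0.44 and 0.48 across genes. D1709N and G1809R shared 204 higher and 108 lower genes against WT and none opposite. Independent lists would share 2.49 and 0.978, and r was 0.86 against 0.50 simulated (covariance 0.132 and 0.0214). With the block they shared 1279 and 1287 genes (110 and 129 for independent lists). Part of this excess, too, may come from the shared WT arrays, whose 3 arrays cannot be split in this way.

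Single arrays moved these counts. For D1709N the count was 3.79 times smaller without D1709N replicate 1, 41 and 83 without D1709N replicates 2 and 3, 265 and 266 without G1809R replicates 1 and 3, 248 without GFP replicate 3, and 84 and 89 without WT replicates 1 and 2. For G1809R it was 3.71 times smaller without G1809R replicate 1, 70 and 102 without G1809R replicates 2 and 3, and 128, 105 and 226 without WT replicates 1, 2 and 3. For the mean of the mutants it was 478 and 542 without D1709N replicates 2 and 3, 560 without G1809R replicate 2, and 324 and 318 without WT replicates 1 and 2. Lin28a (2.47 ± 0.28 SE with D1709N, adjusted p = 0.00644, and 2.60 ± 0.28 with G1809R, adjusted p = 0.00473), Lin28b (1.93 ± 0.25, adjusted p = 0.00924, and 1.80 ± 0.25, adjusted p = 0.0116), Nr6a1 (2.23 ± 0.27, adjusted p = 0.00657, and 2.38 ± 0.27, adjusted p = 0.00557), E2f2, Cdc25a, Tnrc6a, Fstl1 (−2.47 ± 0.24, adjusted p = 0.00276, and −2.65 ± 0.24, adjusted p = 0.00208) and Lrrc15 (−2.66 ± 0.26, adjusted p = 0.00276, and −2.61 ± 0.26, adjusted p = 0.00344) were called in every fit that left out 1 array. Lrrc15 was well above background on 2 of 3 D1709N arrays. Stmn4 (−3.03 ± 0.45, adjusted p = 0.0163, and −3.15 ± 0.45, adjusted p = 0.0132) was not: its adjusted p was 0.0807, 0.065, 0.0592 and 0.0509 without D1709N replicate 2 or 3 or WT replicate 1 or 2. For G1809R it was 0.0631 and 0.0545 without G1809R replicate 2 or 3. Fabp4, a fatty acid-binding protein, was not well above background with a mutant and was at least 1.79-fold lower with D1709N (adjusted p = 0.0318) and at least 2.72-fold lower with G1809R (adjusted p = 0.00758). The D1709N call of Fabp4 was lost without D1709N replicate 1 (0.0724), 2 (0.128) or 3 (0.0811), G1809R replicate 2 (0.0513) or 3 (0.0536), GFP replicate 3 (0.0535), or WT replicate 1 (0.106) or 3 (0.0754).

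The cell cycle list was higher with both mutants than with WT, by means of 0.68 ± 0.04 and 0.72 ± 0.05 (SD of 3 pairs, 3 of 3, adjusted p = 3.21e-33 and 5.57e-40, and with an estimated correlation adjusted p = 0.00463 and 0.0024, or 0.108 and 0.0917 with the block as well). Of 47 members 16 were higher with D1709N and 18 with G1809R, 37 and 38 adjusted over the list alone, and 36 and 38 with the replicate block. Ccna2 was 2.53-fold higher with G1809R (1.34 ± 0.11 SE, adjusted p = 0.00116) and Ccne2, an S phase cyclin, 2.85-fold higher with D1709N (1.51 ± 0.25, adjusted p = 0.0223, lost without D1709N replicate 2 or 3 or WT replicate 1 or 2, at 0.1, 0.0882, 0.0797 and 0.0937). For the mean of the mutants 28 members were higher (mean 0.70, adjusted p = 3.08e-36, and adjusted p = 0.00341 with an estimated correlation, or 0.0969 with the block as well), 39 adjusted over the list alone and 40 with the block.

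The let-7 list was higher by 0.47 ± 0.12 and 0.49 ± 0.07 (3 of 3 pairs, adjusted p = 8.95e-12 and 2.19e-13), with an estimated correlation adjusted p = 0.0511 for D1709N and 0.0348 for G1809R (0.0917 with the block as well). Of 45 members 7 and 8 were higher, 15 and 18 adjusted over the list alone with 1 lower in each, and with the block 19 and 22 higher with 4 and 3 lower. All 5p targets were higher by 0.24 ± 0.07 and 0.24 ± 0.05 (adjusted p = 1.57e-08 and 3.2e-08, and with an estimated correlation adjusted p = 0.0689 and 0.0798). Of 163 members 14 were higher with each and 1 lower with D1709N, 26 and 27 higher and 2 and 2 lower adjusted over the list alone, and with the block 43 and 41 higher and 13 and 10 lower. The miRNA factors (0.39 ± 0.10 and 0.36 ± 0.08), miR-30 (0.28 ± 0.04 and 0.26 ± 0.05), miR-15/16 (0.17 ± 0.06 and 0.20 ± 0.07) and miR-21 targets (0.19 ± 0.07 and 0.18 ± 0.03) were higher too, with adjusted p between 4.8e-05 and 0.0323, but with an estimated correlation adjusted p = 0.0689 and 0.0854, 0.0662 and 0.0798, 0.302 and 0.322, and 0.271 and 0.322. The miRNA factors without Lin28a and Lin28b were at 0.21 and 0.18 (adjusted p = 0.00385 and 0.0102, and with an estimated correlation adjusted p = 0.214 and 0.263). With the replicate block the calls were lost for miR-15/16 with D1709N (0.0523) and miR-21 with G1809R (0.0594). The miR-30 call for G1809R was lost without WT replicate 1 (0.0829). The miR-21 call was lost without G1809R replicate 3 (0.0787), WT replicate 1 (0.0964) or WT replicate 2 (0.0557). The miR-17 family list passed for D1709N (0.14, adjusted p = 0.0173, and adjusted p = 0.302 with an estimated correlation) and not without WT replicate 1 (0.133) or for G1809R (0.10, adjusted p = 0.0779). Hmga2 was at 0.69 ± 0.18 and 0.73 ± 0.18 (0.106 and 0.0973, or 0.0165 and 0.0145 with the block). The miR-34 and miR-31 lists were not called (0.09 and 0.10 with D1709N, 0.11 and 0.05 with G1809R).

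All 3p targets were at −0.13 ± 0.04 and −0.09 ± 0.04 against WT and not called (adjusted p = 0.459 and 0.612). Of 100 members 4 and 4 were higher and none lower, 9 and 8 higher and 3 and 3 lower adjusted over the list alone, and with the block 13 and 14 higher and 18 and 19 lower. The miR-200 list passed with the replicate block only (mean −0.22 and −0.18, 0.121 and 0.198 without it, 0.0495 and 0.0478 with it, and with an estimated correlation in the blocked fit adjusted p = 0.195 and 0.179), as did the miR-29 list with D1709N (−0.27, 0.103 without it, 0.0495 with it, and adjusted p = 0.195 with an estimated correlation in the blocked fit). The miR-19, miR-27, miR-221, miR-101 and miR-25/92 lists, and miR-29 with G1809R, lay between −0.17 and 0.15 and were not called.

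Interferon-stimulated genes were lower with the mutants than with WT (−1.23 ± 0.92 and −0.76 ± 0.87, 3 of 3 pairs, adjusted p = 2.49e-08 and 0.00021, and with an estimated correlation adjusted p = 0.526 and 0.671). The pairs of replicate 1, with the WT array that stood apart, gave −2.28 and −1.76. Those on slide 2 gave −0.86 and −0.55 with D1709N and −0.32 and −0.20 with G1809R. The G1809R call was lost without WT replicate 2 (0.114). By limma 0 of 36 members were called over all genes or over the list alone, and 13 and 2 were lower with the block. Hypoxia and glycolysis genes were higher (0.36 ± 0.34 and 0.26 ± 0.35, adjusted p = 4.8e-05 and 0.00419, and with an estimated correlation adjusted p = 0.424 and 0.486), with 0.68 and 0.59 for replicate 1 and 0.01 and −0.11 for replicate 3. The G1809R call was lost without WT replicate 1 (0.22). Wnt targets were lower (−0.36 ± 0.13 and −0.41 ± 0.10, adjusted p = 0.0294 and 0.0102, and with an estimated correlation adjusted p = 0.185 and 0.0854), but for D1709N not without D1709N replicate 1 (0.0963) or 2 (0.0629), WT replicate 1 (0.0507) or 3 (0.102), or the 2 let-7 targets on the list (0.059). Oncofetal genes (0.25 ± 0.13 and 0.29 ± 0.04, adjusted p = 0.0275 and 0.0243, and with an estimated correlation adjusted p = 0.464 and 0.474) lost the call without WT replicate 2 (0.0698 and 0.0781), D1709N replicate 1 (0.102) or G1809R replicate 1 (0.0984). Without their 6 let-7 targets their means were −0.20 and −0.12 (adjusted p = 0.839 and 0.889). Cholesterol synthesis genes (0.19 ± 0.12 and 0.21 ± 0.12, adjusted p = 0.0289 and 0.0132, and with an estimated correlation adjusted p = 0.564 and 0.486) lost it for D1709N without D1709N replicate 1 (0.202) or 3 (0.106) or WT replicate 1 (0.142) or 2 (0.0551). For G1809R it was lost without G1809R replicate 3 (0.219) or WT replicate 1 (0.0829). Ribosomal proteins were higher with D1709N (0.14 ± 0.17, adjusted p = 0.00674, but a shift of −0.004 with quantile scaling, and adjusted p = 0.765 with an estimated correlation), not without D1709N replicate 2 (0.225) or 3 (0.0611) or WT replicate 1 (0.193). The TGF-beta list (0.00852) and gonadal markers (0.0478) passed with the block for G1809R only, and endothelial markers with the block for both (0.0495 and 0.0478), with an estimated correlation in the blocked fit adjusted p = 0.128, 0.179, 0.195 and 0.179. Their means were −0.36, −0.28, −0.36 and −0.35, and their adjusted p without the block 0.0787, 0.0787, 0.121 and 0.0645. The mesenchymal, smooth muscle, collagen, NF-kB, p53, heat shock, amino acid stress, epithelial, Muellerian and leukocyte lists were not called with either mutant against WT.

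For the mean of the mutants against WT, 13 lists passed, 11 higher and 2 lower. All 5p targets were 0.24 higher (adjusted p = 1.55e-08, and adjusted p = 0.0722 with an estimated correlation), with 22 of 163 members higher and 2 lower, and 53 and 16 with the block. The let-7 list was 0.48 higher (adjusted p = 1.4e-12, and adjusted p = 0.042 with an estimated correlation, or 0.0969 with the block as well), with 13 of 45 higher and 1 lower, and 24 and 5 with the block. All 3p targets were at −0.11 (adjusted p = 0.475). Hypoxia genes (0.31), miRNA factors (0.38), oncofetal genes (0.27), cholesterol synthesis (0.20), miR-30 (0.27), miR-15/16 (0.18), miR-21 (0.19) and miR-17 family targets (0.12) were higher, and interferon genes (1.99-fold on the mean) and Wnt targets (−0.39) lower, at adjusted p from 1.08e-06 to 0.0354. With an estimated correlation, in that order, adjusted p = 0.455, 0.0831, 0.455, 0.549, 0.0722, 0.305, 0.293, 0.317, 0.551 and 0.113. With the replicate block the miR-15/16 (0.0516) and miR-17 family (0.0915) calls were lost, and ribosomal proteins (0.09), endothelial markers (−0.36), miR-200 targets (−0.20), each at 0.046, and the TGF-beta list (−0.32, 0.0397) passed (0.0718, 0.0783, 0.145 and 0.159 without it), with an estimated correlation in the blocked fit adjusted p = 0.774, 0.195, 0.195 and 0.195. The miR-17 family call was lost without D1709N replicate 2 (0.0509) or 3 (0.0534), G1809R replicate 2 (0.0519) or 3 (0.0611), or WT replicate 1 (0.187) or 2 (0.0856). Without WT replicate 1 the miR-30 (0.0573), miR-21 (0.0715), cholesterol (0.0983) and hypoxia (0.0652) calls were lost too. Leaving out members on the let-7 list put oncofetal genes at −0.16 (0.906) and miRNA factors at 0.20 (0.00676, and adjusted p = 0.216 with an estimated correlation). The oncofetal call was lost without G1809R replicate 1 (0.0614) or 3 (0.0529) or WT replicate 2 (0.0856), the cholesterol call without G1809R replicate 3 (0.0862) and the Wnt call without WT replicate 3 (0.0576).

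**Figure D4:**
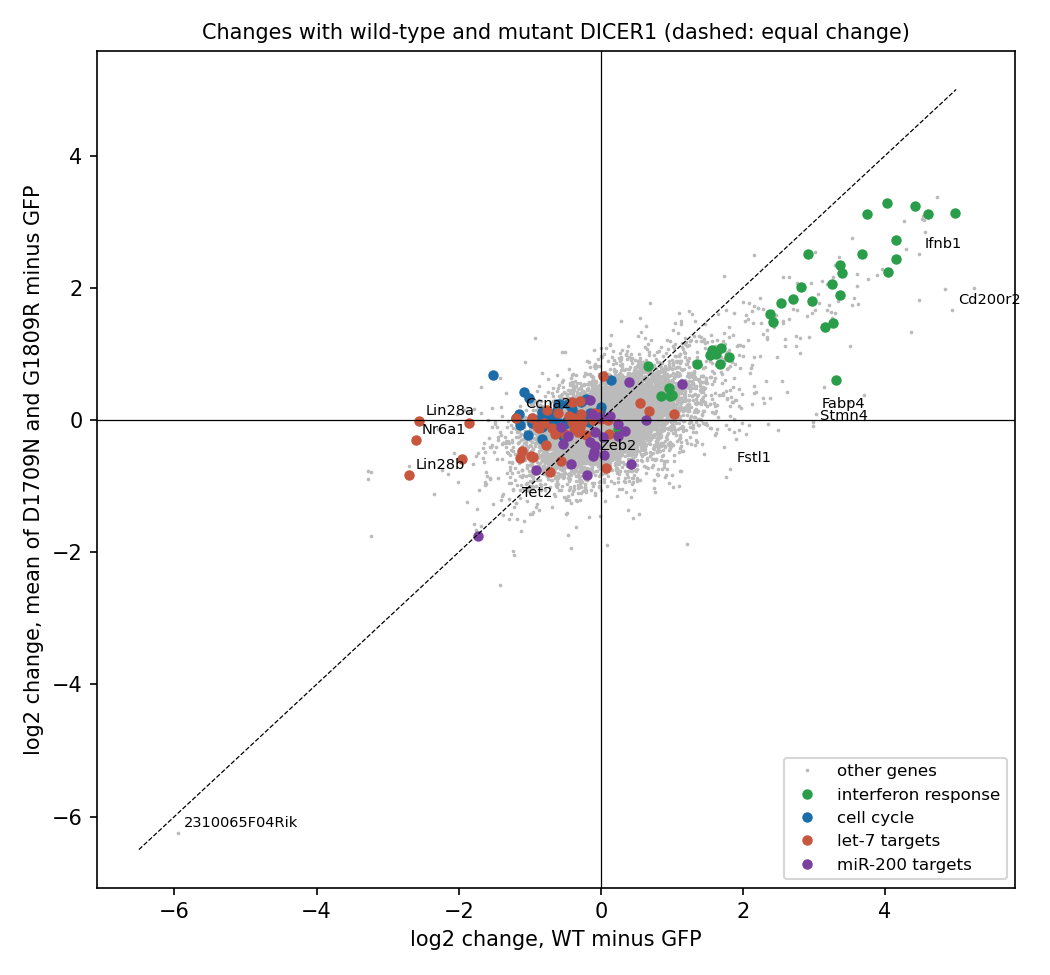
Log2 change of each of 24183 genes with WT against GFP (x axis) and with the mean of the mutants against GFP (y axis), with members of the interferon, cell cycle, let-7 and miR-200 lists coloured and a dashed line at equal change. Cell cycle genes lie to the left, at a mean of −0.63 on the x axis.

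Between the mutants themselves, no gene was called. Lin28b was at 0.13 ± 0.25 (SE, D1709N minus G1809R), Zeb2 at −0.10 ± 0.12 and Hmga2 at −0.03 ± 0.18, each with an adjusted p of 1. Limma called 0 of 24183 genes, 65 had an unadjusted p under 0.05, and the smallest adjusted p was 1. Limma also called 0 with the replicate block, with 1063 under 0.05 and a smallest adjusted p of 0.608. The 95% interval of a gene's difference had a median width of ± 0.47 on the log2 scale, or ± 0.27 with the block, before any adjustment for the number of genes. The genes with the smallest p were Tpsg1 (at least 4.26-fold brighter with D1709N, where it was above background on all 3 arrays, and on none with G1809R), 1500009L16Rik (at least 1.25-fold brighter with G1809R), Fut4 (−0.48 ± 0.14), Homer1 (−0.44 ± 0.10) and Armh3 (−0.44 ± 0.13), all with an adjusted p of 1.

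As groups, interferon-stimulated genes were lower with D1709N than with G1809R (−0.47 ± 0.11, 3 of 3 pairs, adjusted p = 1.87e-05), and ribosomal protein genes (0.10 ± 0.08, adjusted p = 5.08e-06) and hypoxia and glycolysis genes (0.10 ± 0.02, adjusted p = 0.00114) were higher, each with adjusted p = 0.956 with an estimated correlation. Limma called 0 members of these lists, over all genes, over the list alone or with the block. The interferon call was lost without D1709N replicate 1 (0.8) or 3 (0.0556) or G1809R replicate 2 (0.813), where the shift turned to 0.11. The ribosomal call was lost without D1709N replicate 2 (0.401) or G1809R replicate 1 (0.174), where it turned to −0.10. The hypoxia call was lost without D1709N replicate 1 (0.379) or G1809R replicate 2 (0.295). The let-7 list was at −0.02, all 5p targets at 0.00, all 3p targets at −0.03 and cell cycle genes at −0.04, none called.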

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

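The tests in the replicate block without WT replicate 1 were chosen after that array was seen to stand apart, as were those of lists without their let-7 members after these were seen, and all other settings here had been planned. Normexp correction, quantile normalization, the deposited table, the filter over all 12 arrays, trend and robust moderation and the probe level kept each count of changed genes within 1.5 times, apart from G1809R against GFP (3 genes), which gave 6 with normexp and 1 at the probe level. With the mean over a gene's kept probes D1709N against GFP gave 3 and G1809R against GFP 1. The normexp, quantile and deposited-table scalings moved the share of higher calls by under 10 percentage points and the median of all genes by under 0.1.

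Counts below are in the order WT, D1709N and G1809R against GFP, then D1709N, G1809R and the mean of the mutants against WT. The replicate block gave 4300, 1028, 904, 3760, 3065 and 4713 genes, and with WT replicate 1 left out as well 3178, 1262, 1082, 2375, 2016 and 2924. The slide block gave 2112, 97, 63, 1407, 1206 and 2213, and slide 2 only 3, 1, 1, 3, 11 and 54, where fewer arrays were tested. Without a filter on dim probes, where more genes were tested, the counts were 206, 2, 1, 55, 68 and 344. With only the groups compared in the fit, which has fewer arrays to estimate the spread, they were 3, 0, 1, 0, 0 and 461 (by limma, with 1529, 2540 and 2089 genes under an unadjusted p of 0.05 where the count was 0). A change of at least 1 on the log2 scale as well left 239 genes for WT against GFP and 151, 147 and 212 for the comparisons with WT. Between the mutants limma called 0 genes in every setting run (65 under an unadjusted p of 0.05 without the block and 1063 with it). With 1 array left out in turn, where a fit with 2 arrays in a group borrows the spread of the others, the counts ranged over 146 to 601, 2 to 8, 1 to 2, 41 to 307, 70 to 314 and 318 to 727.

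The shift of all 5p targets with WT against GFP kept its call with each choice changed alone, but not with the replicate block and an estimated correlation together (adjusted p = 0.0546), with a range of −0.4732 to −0.2799 over arrays left out. That of all 3p targets with WT lost it with an estimated correlation (−0.1758, with −0.2737 to −0.08756 over arrays left out). With an estimated correlation or fry in place of camera, which leave the shift itself in place, the calls were lost for 5p and 3p targets with D1709N (−0.09189 and −0.2519) and with G1809R (−0.1172 and −0.2461). On slide 2 only the 5p call was lost with D1709N (−0.08839), and the cause was not tested. With arrays left out these shifts were −0.1538 to −0.02645 and −0.3191 to −0.1922 with D1709N, and −0.186 to −0.04976 and −0.3203 to −0.1864 with G1809R. Against WT the 5p shifts lost their calls with an estimated correlation (0.2883 with D1709N, 0.263 with G1809R, 0.2757 for the mean of the mutants) and ranged over 0.188 to 0.3813, 0.1627 to 0.3559 and 0.1754 to 0.3686 with arrays left out. Shifts that were not called changed sign without the filter on dim probes for 3p targets against WT (0.006446 with D1709N, 0.1595 with G1809R, 0.08297 for the mean) and for 5p targets between the mutants (−0.1143), and at the probe level for 3p targets between the mutants (0.004947). With arrays left out, the 3p shifts against WT ranged over −0.1643 to 0.02178, −0.1585 to 0.02759 and −0.1614 to 0.02468, and between the mutants 3p targets over −0.07303 to 0.06847 and 5p targets over −0.04212 to 0.0941. The cause of these sign changes was not tested.

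Without their let-7 members the oncofetal genes changed sign in the shift for D1709N, G1809R and the mean of the mutants against WT (−0.1482, −0.09378 and −0.121) and lost the call. The calls of oncofetal genes with WT against GFP and of Wnt targets with D1709N against WT were lost too, and 19 of 24 list calls were kept. In the other settings 3 called lists changed sign. Ribosomal proteins did so with G1809R against GFP under normexp (−0.005101) and quantile normalization (−0.0142), with D1709N against WT under quantile normalization (−0.004372) and between the mutants without the filter (−0.04421), as did hypoxia and glycolysis genes between the mutants without the filter (−0.03983). With arrays left out the ribosomal shift ranged over −0.06821 to 0.3043 with G1809R and −0.1012 to 0.2997 between the mutants, and the interferon shift between the mutants over −0.9651 to 0.1107. The cause was not tested.

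Of 103 list calls, 98 were kept with the replicate block (15 gained), 101 with the slide block, 67 on slide 2 only, 86 with normexp, 88 with quantile normalization, 99 without the filter, 95 with the filter over all 12 arrays, 100 at the probe level, 103 with trend and robust moderation, 87 with the replicate block without WT replicate 1, 43 with fry and 12 with an estimated correlation. Of 99 calls of named genes, the replicate block kept 99 and added 109, the slide block kept 99, normexp 80, quantile normalization 72, no filter 48, the probe level 87, trend and robust moderation 93, slide 2 only 5 and the replicate block without WT replicate 1 98. The filter over all 12 arrays kept the 82 for which it left a value. No named gene changed sign where it was called. The replicate block changed no call of the text other than those given beside it. Signal over background limits dim genes: 33023 of 55681 probes passed the filter.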

Other observations

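The tests of the 9 explanations of patterns below, and the splits of the mutant and WT arrays together, were chosen after the results were seen. With the replicate block a set of genes moved in opposite directions with wild-type and mutant DICER1. Against GFP, the growth factor gene Tgfb2 rose with WT (0.96, limma adjusted p = 0.00121) and fell with D1709N (−0.95, adjusted p = 0.00652) and G1809R (−0.96, adjusted p = 0.0102). Likewise Cnn1, a calponin of smooth muscle, was at 1.11, −0.96 and −1.03, the retinol carrier gene Rbp4 at 1.12, −0.80 and −0.75, and the matrix protein gene Ltbp2 at 0.43, −0.80 and −0.75. E2f2 was at −1.52, 0.67 and 0.68, and Gas1, a growth arrest gene, at −0.35, 0.74 and 0.63, all 6 genes called in all 3 comparisons and chosen after their values were seen. In all, 23 genes were lower with both mutants and higher with WT, and 7 the opposite. Independent lists would give 34.0 and 22.1, no reference for an excess as the GFP arrays are shared.

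Larger classes moved with one kind of construct. Of 2081 genes lower with WT in the blocked comparison, 207 were lower with both mutants too and 925 were higher in both mutants than in WT, 867 of them not called with either mutant against GFP. Of 2219 genes higher with WT, 184 were higher with both mutants and 816 were lower in both mutants than in WT. Of 371 genes lower with both mutants, 207 were lower with WT and 124 were higher in WT than in both mutants. The classes share arrays, so their sizes are not independent.

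As a list, interferon-stimulated genes were higher with WT, D1709N and G1809R than with GFP, but with an estimated correlation adjusted p = 0.215, 0.333 and 0.244, and without the block limma called 6 of 36 members with WT and 0 with either mutant (13 and 27 with the block). A difference between slides was argued against: within a replicate number, where both arrays lie on 1 slide, the lowest of the 9 mean changes was 1.30. Leukocytes in the cultures stay open: the mean of the 7 measured leukocyte markers of 13 rose by at most 0.231, but the markers went both ways, with Csf1r at −0.53, 0.66 and 0.57 with WT, D1709N and G1809R and Cd14 at 0.51, 0.24 and 0.25 (adjusted p = 0.0338 for WT with the block). The DICER1 plasmids as DNA, or their preparation, cannot be told apart from the encoded proteins, because no array had an inactive DICER1 plasmid, and the level of these genes ranged over 1.67 between the GFP arrays themselves. A response to DICER1 expression or its products, whether or not the RNase IIIb site is intact, may explain the rise as well, and was not tested.

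Cell cycle genes fell with wild-type DICER1 and were not called with the mutants, and both mutants differed from WT in the direct tests. With the replicate block and an estimated correlation together these calls were lost (adjusted p = 0.0546 for WT against GFP, 0.108 and 0.0917 for the mutants against WT). A fall in proportion to the interferon rise would give −0.34 with D1709N and −0.45 with G1809R, but the lowest of the 6 mean changes with a mutant was −0.0353. WT replicate 1 alone was argued against by the slide 2 pairs, the smaller fall being −0.513, and an effect of members on 5p lists by the 43 of 47 genes on no such list, with a mean of −0.604. No biological explanation was tested, since neither miRNAs nor cell division were measured.

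Targets of 5p miRNAs fell most with wild-type DICER1, but with an estimated correlation the mutants against WT lost their calls (adjusted p = 0.0689 and 0.0798, and 0.0722 for their mean), as did WT against GFP with the block as well (0.0546). Also, targets of 3p miRNAs fell with both mutants (adjusted p = 0.201 and 0.162 with an estimated correlation) and also with WT (−0.11), with no call for the mutants against WT (adjusted p = 0.459 and 0.612). Without the let-7 list the other 118 targets of 5p miRNAs fell by 0.195 with WT (SD of 3 pairs 0.0342), so let-7 alone was argued against. Permuting the arm labels over the 14 lists gave an exact p of 0.00699 for the difference between arms in the change from WT to the mutants (0.274), although the lists share genes, and the 3p lists for miR-101 (0.14) and miR-25/92 (0.14) lay above the 5p lists for miR-31 (0.08), miR-34 (0.10) and the miR-17 family (0.12). In 10000 random lists of like signal none had as low a mean, a permutation p of 1e-04, the smallest they can give (lowest −0.12 against −0.31 for 5p targets, and −0.08 against −0.22 for 3p targets). Loss of 5p miRNAs with 3p miRNAs kept may explain part of this, a hypothesis from the same data that no measurement of miRNAs tests here.

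For groups of 3 against 3, the 10 splits are too few for a share under 0.05. Only the real split gave as many genes for WT, D1709N and G1809R against GFP (713, 12 and 3, highest other 0). The same held for D1709N and G1809R against WT (402 and 397, highest other 1 and 0). Between the mutants limma called 0 genes in all 10 splits and 0 with the block (65 and 1063 under an unadjusted p of 0.05 in the real split). Among the 4 splits that part all pairs, the blocked counts were 4300, 1028, 904, 3760 and 3065, and the highest other was 0 in each. For the 3 WT arrays against the 6 mutant arrays, a first version with 100 drawn splits had been seen before the scheme was set to all 84 splits and, with the block, to the 27 that take 1 array of each replicate number. Of the 84, 2 gave as many genes as the real split (872), itself included. The other set the replicate 1 arrays, on slide 1, against the rest (5656 genes), which points to a structure by slide. The next, the G1809R arrays, gave 2. With the block the real one of the 27 gave 4713 genes, the D1709N arrays 251, the G1809R arrays 175 and mixed splits 0. Mixing groups adds their difference to the spread, so the low counts above are no reference.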
